A study of Solanum lycopersicum with 21 samples.

How the data were processed

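Ribosomal-RNA-depleted, strand-specific, paired-end RNA libraries of tomato (Solanum lycopersicum) were measured for 7 kinds of sample with 3 biological replicates each, 21 libraries in all: microspores, generative cells, sperm cells, mature pollen grains, pistils, fully expanded leaves and callus. Per the labels' protocols, microspores were pressed out of anthers 5 mm long from flowers 7 mm long, generative cells were taken from pollen cultured for 20 min, and sperm cells from pollen tubes cultured for 10 h. The groups and replicate numbers were taken from the sample titles and sources, and each column of the table was matched to a sample by its title.

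The authors deposited 1 table with a value per feature and library. Its header names no unit. The values are read here as FPKM (fragments per kilobase of transcript, scaled to library size) deposited by the authors, because they are not whole numbers, contain exact zeros and sum to between 250477 and 757249 per library, and because Cuffdiff 2.1.1 is the tool named in the submitters' processing notes. Whether Cuffdiff rescaled libraries against each other, the aligner, and the rule by which features were listed as expressed are not given in the sources used here. The table holds 70911 features, 38980 listed as mRNAs and 31931 as lncRNAs. Of the mRNAs, 22596 carry public tomato gene identifiers (Solyc, called annotated mRNAs below) and 16384 carry identifiers of the authors' own gene models (SlHei, called additional mRNAs). The authors also deposited those gene models as an annotation on build SL2.50, whose start and end coordinates, strands, exons and evidence tags were used as given, per the file headers; 48315 of the table's features were found in it, and none of the Solyc identifiers.

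Neither the files nor the reference gene table used here paired the identifiers with gene names (0 identifiers matched). Only 46 features, 37 mRNAs and 9 lncRNAs, had a Swiss-Prot protein match among the evidence tags, and 35 of these passed the filter. The keyword gene lists fixed before the data were examined could therefore not be formed, and their set tests were not run. In their place, sets of feature classes and a list of 5 features were chosen after seeing the data. The classes were annotated mRNAs, additional mRNAs with complete, partial or short frames, intergenic lncRNAs and lncRNAs overlapping coding gene models. Overlap was judged only against the coding models of the deposited annotation, in which no Solyc identifier was found. The list held features with matches to proteins of organelle genomes or, for 1 of them, of a cyanobacterium. A match is a resemblance to a known protein, not a known function, and reads from near-identical copies may be divided between them in a way that is not stated.

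FPKM values are not counts, so no count test was used. Features with at least 1 FPKM in at least 3 libraries were kept (32849 features, made up of 19848 annotated mRNAs, 5141 additional mRNAs and 7860 lncRNAs). Values were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with 1 mean per group, a mean-variance trend and robust empirical Bayes moderation (statmod 1.5.0). A feature was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1. All log2 fold changes are on this scale and understate the change of features near 0. The 5 comparisons were fixed before the data were examined, each answered from the same fit. A feature was called preferential to a cell type when it passed the threshold upward against each of the other 6. Class sets were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, with adjustment over 35 tests. Expressed features were counted at 1 FPKM and compared with two-sided exact permutation tests, for which 3 libraries against 3 cannot give a p below 0.1. Cell-type specificity was the tau index over the 7 group means of log2(FPKM + 1), compared between classes with a two-sided permutation test (100000 permutations of the class labels) and again after matching on the highest group mean. These permutations and the Fisher's exact tests between classes treat features as independent replicates, which they are not. Their p-values are therefore likely too small and their intervals too narrow. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the rest.

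Replicates were compared before they were averaged. The low values of each library are spaced by what 1 fragment is worth, which gave approximate depths between 27700000 and 51700000 fragments and a floor between 0.0193 and 0.0362 FPKM per fragment for a 1-kb feature. With these approximate fragments, callus libraries 2 and 3 did not differ detectably beyond sampling noise (chi-square per feature 1.06 over 1098 features, p = 0.0839), whereas callus library 1 differed from each of them by 6.76 and 6.81. Callus 2 and 3 were counted as 1 sample by their mean, so that callus has n = 2 and the fit has 20 columns, a departure from the planned 21; the fit with both kept apart is an added alternative. All other pairs differed by more than sampling noise in this test. By the median chi-square over its expectation, pistil 2 and 3 (1.022) and leaf 1 and 2 (1.035) were as close as callus 2 and 3 (1.043). The choice to merge only the callus pair thus rests on the mean chi-square.

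The test was tried on simulated libraries built on the real microspore means for the comparison of generative cells with microspores (32849 features, 100 changed 4-fold and 100 changed 8-fold). It recovered 81% of the first and 97% of the second, none in the wrong direction, and called 32 of the 32649 unchanged features. The simulation had a dispersion of 0.1, as many features raised as lowered and no shift of scale between groups. Changed features were drawn from those at 1 FPKM or more in microspores. The real comparison had a median log2 fold change of -0.86, so the simulated rate of false calls need not carry over to it. Among the unchanged features 9.65% had an unadjusted p under 0.05, above the nominal share, so some p-values are too small; the reason was not tested.

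The described mRNAs named per comparison follow a rule fixed beforehand. It takes up to 8 in each direction, with the largest change among those past the threshold. The libraries compared must not overlap, and the mean must be at least 5 FPKM in the higher group. Here described means having a Swiss-Prot match, which left fewer than 8 in most cases. Features without a description were outside that rule and are printed by identifier only, at most 2 in each direction. For preferential features the rule allowed more mRNAs per cell type, of which 1 is named beside 1 lncRNA. The organelle matches and the most abundant features were also outside the rule. The alternatives were another pseudocount (0.1), no filter, quantile and upper-quartile scaling, a fit of the compared groups alone, the replicate number as a block, array weights (estimated gene by gene, since the default estimate did not converge), no fold threshold and each replicate left out in turn. Alternatives chosen after seeing the data were callus 2 and 3 kept apart, scaling within groups, and the removal of features listed at 0 beside at least 100 FPKM in another library of the group. The upper quartile of kept features averaged 0.481 FPKM in mature pollen, 1.78 in sperm cells and 1.92 in generative cells. It averaged 5.33 in leaf, 7.33 in microspores, 9.14 in callus and 10.6 in pistil. Upper-quartile scaling therefore rests on low values in the first groups and raises them against the others.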

Results

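Transcript levels were measured in 21 RNA libraries along the sperm cell lineage of tomato and in sporophytic material. The uninucleate microspore divides into a large vegetative cell and a small generative cell enclosed in it, and the generative cell later divides in the growing pollen tube to give the sperm cells. Microspores, generative cells, sperm cells and mature pollen grains represent this lineage, and pistil, leaf and callus (unorganised tissue grown from hypocotyls) represent sporophytic tissue, each with 3 libraries. Isolation and culture differed with the cell type, so differences between cell types cannot be told apart from effects of handling. The deposited FPKM values covered 38980 mRNAs and 31931 lncRNAs, and the approximate depth lay between 27700000 and 51700000 fragments per library. Callus libraries 2 and 3 did not differ detectably beyond sampling noise and were counted as 1 sample, so n = 2 for callus and n = 3 for every other group.

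At 1 FPKM or more, fewer features were expressed in generative cells, sperm cells and mature pollen than in microspores. Microspores had 18150 ± 447 mRNAs and 5437 ± 720 lncRNAs (SD, n = 3), close to the 17892 ± 53.7 mRNAs of pistil but with more lncRNAs than the 2689 ± 75.5 found there. Generative cells had 8830 ± 89.9 mRNAs and 3038 ± 133 lncRNAs, sperm cells had 7737 ± 2039 mRNAs and 3041 ± 993 lncRNAs, and mature pollen had 5911 ± 729 mRNAs and 829 ± 17.4 lncRNAs. The generative cell had 0.487 times as many mRNAs and 0.559 times as many lncRNAs as the microspore, with no overlap between libraries (exact permutation p = 0.1 for each, the smallest that 3 against 3 allows). Sperm and generative cells were not told apart in mRNA number (exact permutation p = 0.4) or lncRNA number (exact permutation p = 1), and the sperm cell libraries ranged from 5739 to 9814 mRNAs. This held at 1 FPKM but not at 0.1 FPKM, where every sperm cell library had fewer mRNAs and lncRNAs than every generative cell library. Generative cells had 3.66 times as many lncRNAs as the mature grain that encloses them and 1.49 times as many mRNAs (exact permutation p = 0.1 for each).

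**Figure D1:**
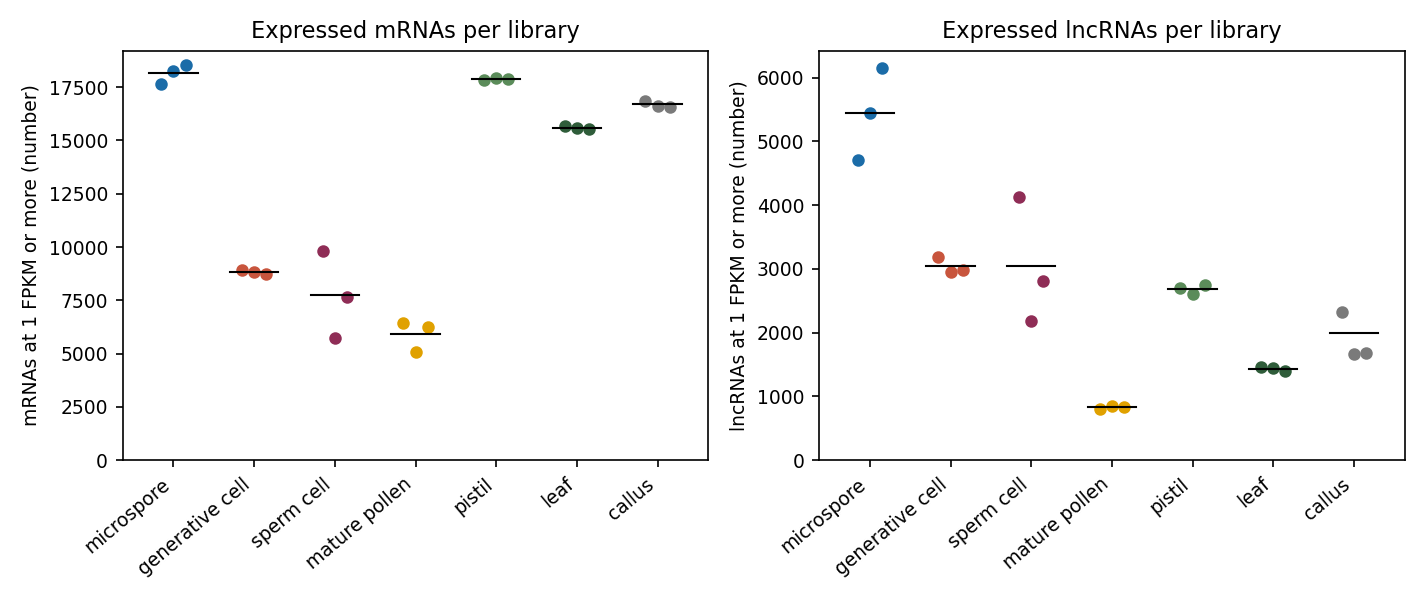
Number of mRNAs (left) and lncRNAs (right) with at least 1 FPKM in each library. Points are libraries and bars are group means, in which callus 2 and 3 count as 1 sample; microspores average 18150 mRNAs and mature pollen 5911.

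Libraries of 1 group resembled each other more than those of other groups. The mean Pearson correlation of log2(FPKM + 1) over features, which are not independent replicates, lay between 0.9587 for sperm cells and 0.9965 for pistil within groups. Generative and sperm cells were close to each other (mean correlation 0.824) and far from microspores (0.314 for the generative cell and 0.19 for the sperm cell). The first principal component held 56.5% of the variance and separated generative cells, sperm cells and mature pollen from microspores and sporophytic tissue, while the second held 13.4% and the third 11.8%. Some libraries stood apart inside their group. Sperm cell library 2 lay below sperm cell library 1 across features of 10 to 100 FPKM, by a median log2 ratio of 1.665, and mature pollen library 2 lay below library 1 by 1.14.

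**Figure D2:**
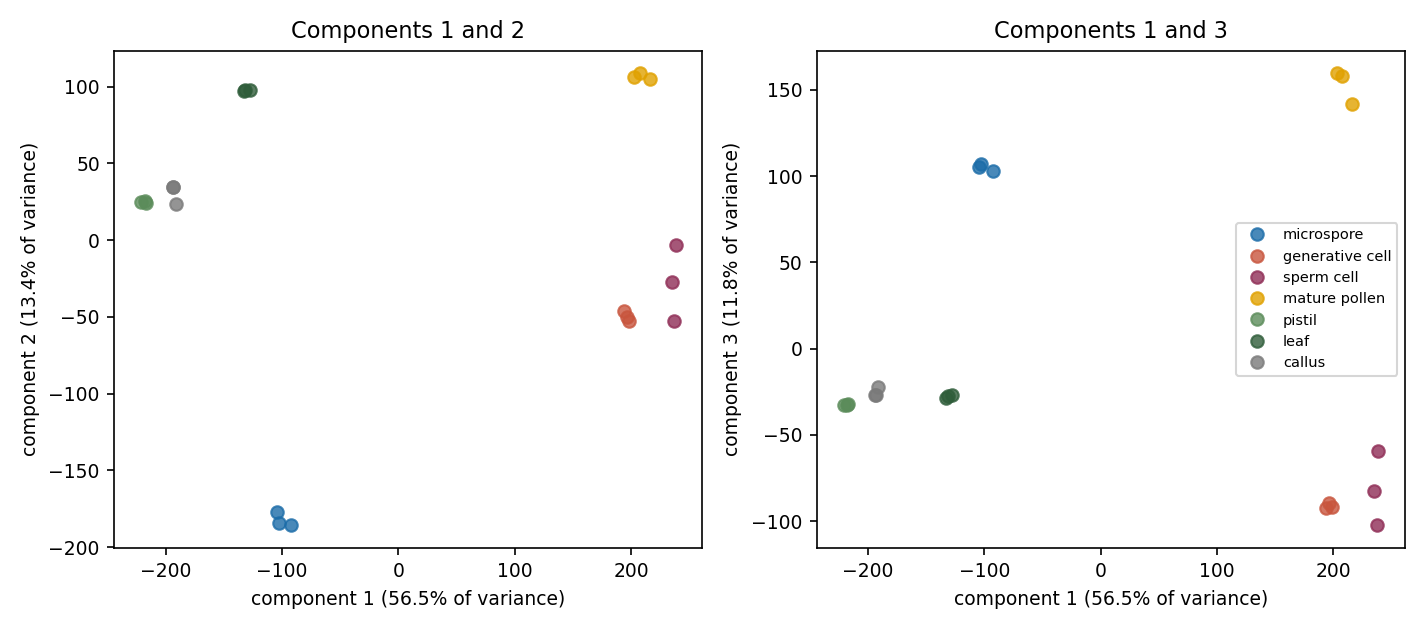
Principal components of log2(FPKM + 1) over 32849 features, components 1 and 2 on the left and 1 and 3 on the right. Each point is 1 library; the 3 sperm cell libraries spread more than the 3 generative cell libraries.

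The first step of the lineage was addressed by comparing generative cells with microspores. Generative cells came from pollen cultured for 20 min and microspores were pressed out of anthers, so cell type and handling cannot be told apart here. The largest rises among annotated mRNAs were Solyc08g062200, which went from 0.254 ± 0.111 FPKM in microspores to 1571 ± 91.3 FPKM in generative cells (SD, n = 3 each), and Solyc03g098350, which went from 0.166 ± 0.0982 to 1229 ± 46.4 FPKM. Among mRNAs with a protein match, the one resembling a subunit 5C of cytochrome c oxidase (COX5C_ORYSJ), the terminal enzyme of mitochondrial respiration, rose from 0.478 ± 0.0802 to 7.48 ± 0.402 FPKM (log2 fold change 2.52, SE 0.25, limma adjusted p = 7.47e-08). An mRNA matching the heat stress transcription factor HSF30_SOLPE rose from 2.16 ± 0.302 to 9.21 ± 0.425 FPKM (1.70, SE 0.19, limma adjusted p = 3.13e-07), and one matching the plastid chaperone CLPB3_ARATH rose from 2.40 ± 0.161 to 11.2 ± 4.98 FPKM. The size of these rises depended on the scaling: the log2 fold change for HSF30_SOLPE was 2.91 under quantile normalization and 3.09 under upper-quartile scaling, and for CLPB3_ARATH it went from 1.75 to 2.95 and 3.16. An mRNA matching the callose synthase CALS9_ARATH stood at 6.91 ± 1.25 FPKM against 2.22 ± 1.48 FPKM (limma adjusted p = 0.018), but this call was lost without microspore library 2 (log2 fold change 1.01), without generative cell library 2 (1.28) and with a pseudocount of 0.1 (1.83). Its log2 fold change was 1.40, and 2.59 and 2.71 under the 2 scalings.

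Among the mRNAs lower in generative cells than in microspores, an mRNA matching a protein phosphatase 2C (P2C43_ORYSJ), a class of enzymes that removes phosphate from serine and threonine, fell from 172 ± 83.4 FPKM in microspores to 0.0432 ± 0.0106 FPKM (log2 fold change -7.26, SE 0.23, limma adjusted p = 3.93e-14). mRNAs matching methylmalonate-semialdehyde dehydrogenase (MMSA_ARATH, valine breakdown), dihydroorotase (PYRC_ARATH, pyrimidine synthesis), the N-acetylglucosamine transferase SEC_ARATH and the Sec61 beta subunit of the protein translocation channel (SC61B_ARATH) fell too, with log2 fold changes of -4.79, -3.34, -4.17 and -4.12. So did mRNAs matching germacrene C synthase (TPSGC_SOLLC, a sesquiterpene enzyme), from 8.81 ± 1.31 to 0.239 ± 0.0747 FPKM, and the calcium-binding protein CML16_ARATH, from 8.62 ± 1.65 to 1.16 ± 0.25 FPKM; the CML16 call was lost under quantile (log2 fold change -0.67) and upper-quartile scaling (-0.70). The mRNA matching the plastid reading frame YCF15_HELAN (chromosome 1, 1896061 to 1903191, plus strand, build SL2.50) fell from 603 ± 86.6 to 29.6 ± 20.1 FPKM; its reads may be shared with the plastid genome. Falls were smaller for PYRC_ARATH (-2.15) and TPSGC_SOLLC (-1.71 instead of -2.98) under quantile normalization, and for YCF15_HELAN under upper-quartile scaling (-2.58 instead of -4.48). The annotated mRNA Solyc09g097940 fell from 418 ± 13.03 to 0.0449 ± 0.00564 FPKM. The additional mRNA SlHei09G26171300.01 (chromosome 9, 70363809 to 70364112, 1 exon) was listed at 58441, 48497 and 40053 FPKM in the microspore libraries and at 0 in all generative cell libraries, and because such zeros also occur beside high values within a group, only the listing is reported.

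Of 32849 features tested, 4825 were higher and 15454 lower in generative cells than in microspores, and 12570 passed in neither direction. Among the 29 mRNAs with a protein match, 5 rose and 12 fell. Annotated mRNAs were mostly lower (1796 higher and 10612 lower of 19848), whereas lncRNAs divided more evenly (1803 higher and 3021 lower of 7860). The share called higher was 22.9% for lncRNAs against 9.05% for annotated mRNAs (Fisher's exact odds ratio 2.99, 95% interval 2.78 to 3.22), but additional mRNAs, at 23.8%, did not differ from lncRNAs in this share (odds ratio 0.951, 0.874 to 1.03). They were called lower less often than lncRNAs, in 35.4% against 38.4% (odds ratio 1.14, 1.06 to 1.23, adjusted p = 0.000949). Of the 2258 lncRNAs and additional mRNAs without the evidence tag test_wlq, taken up at the end, 8.95% were called higher. This did not differ from annotated mRNAs (odds ratio 0.988, 0.844 to 1.15). Relative to other features, annotated mRNAs ranked lower as a class (camera adjusted p = 2.12e-07), a call not kept with an estimated correlation (adjusted p = 0.767 with an estimated correlation). The median log2 fold change of all features was -0.86. With upper-quartile scaling it was -0.16 and the calls became 7994 higher and 8451 lower, and with quantile normalization 8413 higher and 8233 lower, so the excess of lower calls holds for FPKM as deposited.

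The second step compared sperm cells with generative cells, in which fewer features changed. Sperm cells came from pollen tubes cultured for 10 h and generative cells from pollen cultured for 20 min, so cell type goes together with culture time. The annotated mRNA Solyc03g121150 rose from 8.54 ± 0.818 FPKM in generative cells to 693 ± 102.5 FPKM in sperm cells (SD, n = 3 each; log2 fold change 6.18, SE 0.18, limma adjusted p = 1.03e-12) and stayed at or below 1.051 FPKM in every other group mean. The additional mRNA SlHei01G03003700.01 (chromosome 1, 59313699 to 59313943, plus strand, 1 exon) rose from 0.191 ± 0.331 to 68.3 ± 49.2 FPKM. The HSF30_SOLPE match, highest in generative cells, fell back from 9.21 ± 0.425 to 0.455 ± 0.267 FPKM (log2 fold change -2.83, SE 0.19, limma adjusted p = 5.22e-09). The largest falls among called mRNAs without overlap between libraries were Solyc12g039030, from 855 ± 284 to 23.4 ± 18.5 FPKM, and Solyc01g048590, from 229 ± 82.1 to 9.23 ± 7.77 FPKM. Both were most abundant in leaf, at 108110 ± 5819 and 64181 ± 306 FPKM.

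mRNAs matching CML16_ARATH and the lipid-transporting ATPase ALA9_ARATH were higher in sperm than in generative cells, at 5.79 ± 4.10 against 1.16 ± 0.25 FPKM and at 7.51 ± 4.87 against 1.78 ± 0.208 FPKM, and the YCF15_HELAN match was lower, at 6.68 ± 1.89 against 29.6 ± 20.1 FPKM. These 3 calls (limma adjusted p = 0.00289, 0.00245 and 0.00113) were lost when only the compared groups set the spread. In all, 2848 features were higher and 4145 lower in sperm cells, and of the 29 mRNAs with a protein match 2 rose and 4 fell. lncRNAs were called higher in 14.9% of cases, additional mRNAs in 15.3% and annotated mRNAs in 4.49%, while the shares called lower were 12.5%, 12.5% and 12.7%. A fit of these 2 groups alone, which sets the spread from their own libraries, gave 4826 calls instead of 6993. Of these, 1766 were higher and 3060 lower. The balance of directions depended on single sperm cell libraries. Without library 2, 3697 features were higher and 3161 lower, and without library 1, 2093 were higher and 5377 lower.

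The whole grain was compared with the microspore from which it develops. The largest rises among called mRNAs without overlap between libraries were Solyc03g058910, from 6.81 ± 0.963 FPKM in microspores to 5491 ± 2466 FPKM in mature pollen (SD, n = 3 each), and Solyc02g067450, from 3.55 ± 0.497 to 3019 ± 1294 FPKM. The ALA9_ARATH match, a flippase that moves phospholipids between membrane leaflets, rose from 2.29 ± 0.103 to 32.1 ± 13.4 FPKM (log2 fold change 3.24, SE 0.34, limma adjusted p = 1.45e-07), and the CML16_ARATH match rose from 8.62 ± 1.65 to 27 ± 10.1 FPKM (1.48, SE 0.35, limma adjusted p = 0.000916). The size of both changes depended on the scaling: under upper-quartile scaling the log2 fold change was 6.70 for ALA9_ARATH and 5.22 for CML16_ARATH, the latter 2.78 under quantile normalization. The upper quartile that sets this scaling averaged only 0.481 FPKM in mature pollen, against 7.33 FPKM in microspores. In the other direction, an mRNA matching ribosomal protein L32 (RL321_ARATH; chromosome 2, 40781439 to 40782853, plus strand, 5 exons) fell from 1442 ± 49.4 to 12.3 ± 13.5 FPKM, with reads possibly divided among near-identical copies. Its log2 fold change was -7.25, and -3.45 under upper-quartile scaling.

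The YCF15_HELAN, P2C43_ORYSJ, MMSA_ARATH, SEC_ARATH, PYRC_ARATH and TPSGC_SOLLC matches fell between microspores and mature pollen, with log2 fold changes of -7.57, -7.29, -5.59, -4.45, -3.57 and -3.26. Most of these sizes depended on the scaling: with upper-quartile scaling YCF15_HELAN was at -4.13 and MMSA_ARATH at -3.43, and with quantile normalization SEC_ARATH was at -2.61, PYRC_ARATH at -1.94 and TPSGC_SOLLC at -1.84. A match to ferredoxin-dependent glutamate synthase (GLTB1_ARATH, nitrogen assimilation in plastids) fell as well (log2 fold change -2.62), a call lost under quantile normalization (log2 fold change -0.82). The largest falls among called mRNAs without overlap between libraries were Solyc08g075740, from 6536 ± 234 to 13.5 ± 14.7 FPKM, and Solyc11g073200, from 744 ± 118 to 0.226 ± 0.0376 FPKM. Upper-quartile scaling took the log2 fold change of Solyc08g075740 from -9.31 to -5.50. In total 2281 features were higher and 17973 lower in mature pollen, and of the 29 mRNAs with a protein match 2 rose and 16 fell. lncRNAs were called less often than annotated mRNAs in both directions, higher in 5.20% against 8.06% (Fisher's exact odds ratio 0.626, 0.558 to 0.701) and lower in 46.8% against 60.7% (0.570, 0.541 to 0.601). Additional mRNAs were called higher in 5.29% of cases, which did not differ from lncRNAs (odds ratio 0.983, 0.837 to 1.15), and lower in 43.9%, less often than lncRNAs (odds ratio 1.13, 1.05 to 1.21, adjusted p = 0.00175). The median log2 fold change was -1.19, and the 100 most abundant features held 64.6 ± 4.39% of the summed FPKM in mature pollen against 38.5 ± 0.921% in microspores. Upper-quartile scaling gave a median of -0.20 with 6100 higher and 7850 lower, and quantile normalization gave 5648 higher and 6873 lower.

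Generative cells were also set against the mature grain that contains them, which sets the germ cell apart from the vegetative cell that makes up most of the grain. The additional mRNA SlHei08G23563200.01 (chromosome 8, 65470111 to 65474549, minus strand, 2 exons) stood at 1184 ± 94.98 FPKM in generative cells and 0.267 ± 0.0418 FPKM in mature pollen (SD, n = 3 each), and Solyc06g075860 at 633 ± 7.34 against 0.211 ± 0.156 FPKM. The RL321_ARATH match was at 2162 ± 860 FPKM against 12.3 ± 13.5 FPKM (log2 fold change 7.76, SE 0.54, limma adjusted p = 3.7e-09). Matches to CLPB3_ARATH, HSF30_SOLPE, YCF15_HELAN and COX5C_ORYSJ were also higher in generative cells, with log2 fold changes of 3.43, 3.32, 3.09 and 2.90. For YCF15_HELAN it was 1.97 under quantile normalization and 1.55 under upper-quartile scaling. The CALS9_ARATH match was higher too (1.53, SE 0.51, limma adjusted p = 0.0178), a call lost without mature pollen library 2 (0.88), without generative cell library 2 (1.41), under quantile (0.725) and upper-quartile scaling (0.476) and when only the compared groups set the spread.

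Higher in mature pollen were the matches to CML16_ARATH (27 ± 10.1 against 1.16 ± 0.25 FPKM) and ALA9_ARATH (32.1 ± 13.4 against 1.78 ± 0.208 FPKM), the additional mRNA SlHei04G13490000.01 (1489 ± 712 against 11.3 ± 1.46 FPKM) and Solyc05g054160 (1192 ± 798 against 12.3 ± 1.89 FPKM). Upper-quartile scaling enlarged the log2 fold change from -3.63 to -5.92 for CML16_ARATH and from -3.48 to -5.71 for ALA9_ARATH. Of all features, 7919 were higher and 3663 lower in generative cells, with 8 higher and 3 lower among the 29 mRNAs with a protein match. The share called higher was 29.8% for lncRNAs, 31.3% for additional mRNAs and 20.0% for annotated mRNAs. With upper-quartile scaling the calls were 7500 higher and 6690 lower, and with quantile normalization 7507 higher and 6865 lower.

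Sperm cells were last compared with the mean of leaf, callus and pistil. Solyc00g024160 reached 4156 ± 2483 FPKM in sperm cells against 2.16 ± 0.159 in leaf, 0.262 ± 0.0854 in pistil and 0.705 ± 0.49 in callus (SD, n = 3, callus n = 2), and Solyc03g019990 reached 1989 ± 1072 FPKM against at most 0.71 FPKM in those group means. Of the mRNAs with a protein match, those to CML16_ARATH (log2 fold change 2.38, SE 0.29, limma adjusted p = 8.3e-07) and RL321_ARATH (2.24, SE 0.45, limma adjusted p = 0.00024) were higher in sperm cells. Matches to YCF15_HELAN, the vacuolar aquaporin TIP21_ARATH, SEC_ARATH and the lamin-like protein LAML_ARATH were lower by more, with log2 fold changes of -5.67, -5.14, -5.05 and -4.93, followed by MMSA_ARATH, SC61B_ARATH, PYRC_ARATH and GLTB1_ARATH matches at -3.40, -3.10, -2.93 and -2.78. The sizes depended on the scaling: upper-quartile scaling gave 4.60 for RL321_ARATH and -3.39 for YCF15_HELAN, and quantile normalization gave -1.79 for MMSA_ARATH, -1.24 for SC61B_ARATH, -1.55 for PYRC_ARATH and -1.13 for GLTB1_ARATH. Solyc09g059660 stood at 1.51 ± 1.13 FPKM in sperm cells and 8784 ± 692 FPKM in leaf, and Solyc06g007510 at 0.179 ± 0.0989 FPKM in sperm cells and 746 ± 67.1 FPKM in callus.

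Against the sporophytic mean, 5063 features were higher and 15746 lower in sperm cells, and among the 29 mRNAs with a protein match 3 rose and 14 fell. The direction differed by feature class. Of annotated mRNAs 7.95% were higher and 68.5% lower, of lncRNAs 26.8% were higher and 14.8% lower, and of additional mRNAs 26.8% were higher and 19.4% lower. Intergenic lncRNAs carried the lncRNA share, with 2023 higher and 928 lower of 6786. Of 1074 lncRNAs overlapping coding gene models of the authors, 85 were higher and 235 lower. Intergenic here means apart from those models only, since overlap with annotated mRNAs was not checked by their own coordinates. The odds of being called higher were 4.25 times as large for lncRNAs as for annotated mRNAs (Fisher's exact 95% interval 3.95 to 4.56). This excess was not seen in lncRNAs and additional mRNAs without the evidence tag test_wlq, which is taken up at the end. Of these 2258 features 6.51% were called higher, against 7.95% of annotated mRNAs (odds ratio 0.807, 0.673 to 0.962). Intergenic lncRNAs ranked higher than other features (camera adjusted p = 5.05e-20) and annotated mRNAs lower (adjusted p = 1.54e-26), and neither call held with an estimated correlation (adjusted p = 0.374 with an estimated correlation for both). Additional mRNAs with short, complete and partial frames ranked higher as well (camera adjusted p = 3.8e-16, 2.71e-06 and 0.000187), which an estimated correlation did not keep (adjusted p = 0.561, 0.767 and 0.767 with an estimated correlation), and the overlapping lncRNAs did not pass (adjusted p = 0.541). The median log2 fold change was -0.90. With upper-quartile scaling (median -0.23) the calls were 7611 higher and 9701 lower, and with quantile normalization 7938 higher and 9416 lower.

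**Figure D3:**
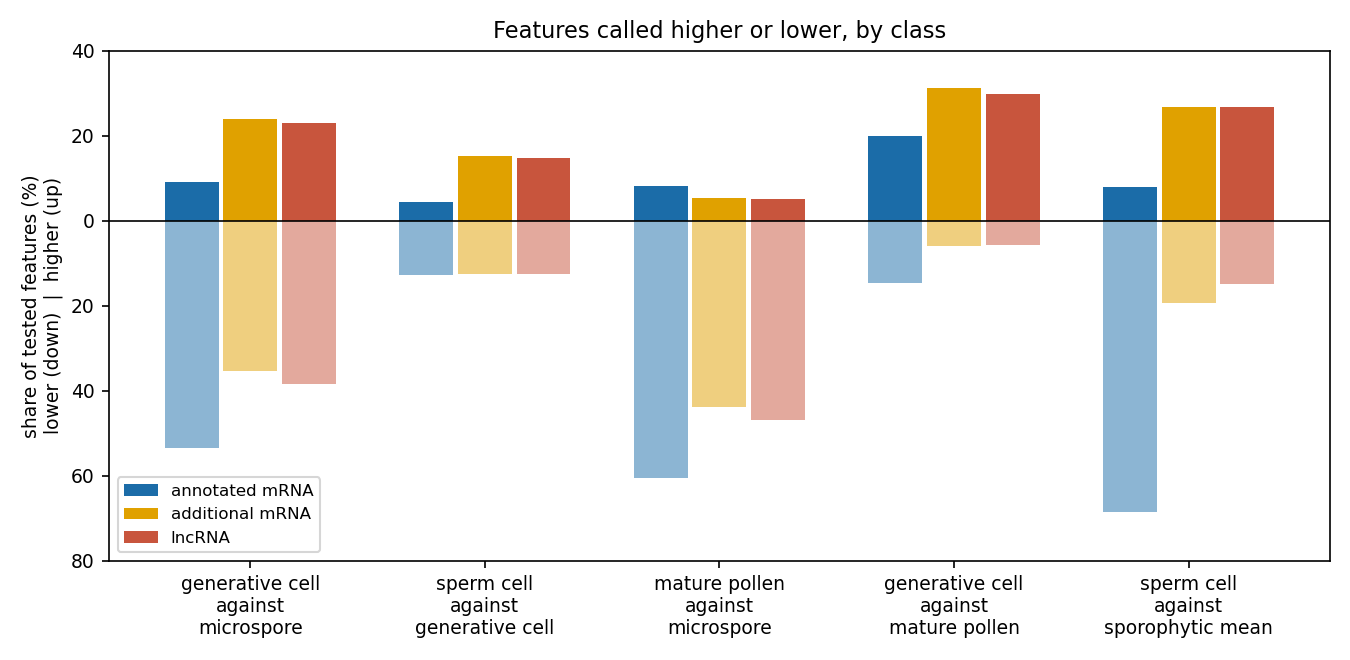
Share of tested features called higher (above the line) or lower (below the line) in the first-named sample of each comparison, as a percentage of the 19848 annotated mRNAs, 5141 additional mRNAs and 7860 lncRNAs tested. lncRNAs and additional mRNAs reach 26.8% higher calls in sperm cells against sporophytic tissue, and annotated mRNAs 7.95%.

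A list of 5 features chosen after seeing the data had matches to proteins encoded in organelle genomes or, for ATPL_TRIEI, to a cyanobacterial protein. ATPL_TRIEI (ATP synthase subunit c) and the plastid-type match PETD_VITVI (a cytochrome b6-f subunit) were highest in leaf, at 17.8 ± 3.4 and 6.84 ± 5.56 FPKM (SD, n = 3), as was YCF15_HELAN at 1247 ± 76.1 FPKM. The mitochondrial-type match ATP6_VICFA (ATP synthase subunit a), which the table lists as an lncRNA, was at 621.5 ± 21.5 FPKM in microspores and 561 ± 43 FPKM in generative cells but at 8.29 ± 2.51 FPKM in mature pollen (log2 fold change against microspores -6.10, SE 0.31, limma adjusted p = 1.57e-11). Of the 5, none rose and 4 fell in mature pollen against microspores, and none rose and 4 fell in sperm cells against the sporophytic mean. The list is a subset: it leaves out RM16_ARATH (mitochondrial ribosomal protein L16) and YCX1_CALFG (a plastid reading frame), both called lower in these 2 comparisons as well. The list as a whole passed in none of the 5 comparisons (camera adjusted p between 0.359 and 0.548).

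Each cell type had features above all 6 others, and the sperm cell's were mostly lncRNAs and additional mRNAs. Microspores had 4403 preferential features, 1949 of them lncRNAs, generative cells 1363 with 566 lncRNAs, and sperm cells 1931 with 1090 lncRNAs and 119 annotated mRNAs. Mature pollen had 1616 with 328 lncRNAs, pistil 2300 with 322, leaf 1394 with 135 and callus 1856 with 202. By a separate count, which may overlap with these, 1953 features, 991 of them lncRNAs, were higher in both generative and sperm cells than in each of the other 5 cell types. lncRNAs thus made up 56.4% of sperm cell features, 44.3% of microspore features and 9.68% of leaf features, against 23.9% of all features tested.

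The leading microspore features were Solyc09g097940 and the lncRNA SlHei09G26238900.01 (chromosome 9, 71340740 to 71341082), the latter at 673 ± 263 FPKM (SD, n = 3). In generative cells they were Solyc08g062450 at 74.8 ± 3.58 FPKM and the lncRNA SlHei05G14056700.01 at 121 ± 7.65 FPKM, the latter on chromosome 5 from 7948192 to 7948589. In sperm cells they were Solyc03g121150 at 693 ± 102.5 FPKM and the 3-exon lncRNA SlHei06G16555900.01 at 58.4 ± 27.2 FPKM, on chromosome 6 from 6684570 to 6685072. The pair of germ cells shared Solyc06g075860, at 633 ± 7.34 FPKM in generative and 1539 ± 297.5 FPKM in sperm cells, and the lncRNA SlHei07G21038500.01, at 403 ± 56.7 and 2997 ± 2193 FPKM. In mature pollen the leading features were Solyc01g099820 at 4855 ± 433 FPKM and the lncRNA SlHei09G23681400.01 at 5822 ± 2877 FPKM. In callus they were Solyc03g096430 at 16097 ± 1386 FPKM and the lncRNA SlHei12G32385100.01, which differed between the callus samples (2252 ± 3130 FPKM, SD, n = 2). Pistil was led by SlHei12G33449100.01 at 2214 ± 156 FPKM and the lncRNA SlHei11G29132200.01 at 252 ± 11.1 FPKM, and leaf by Solyc02g085950 at 10119 ± 384 FPKM and the lncRNA SlHei05G14010900.01 at 161 ± 5.57 FPKM. Under quantile normalization the number for microspores was 2665, for mature pollen 2589, for pistil 1137 and for the germ cell pair 3426.

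**Figure D4:**
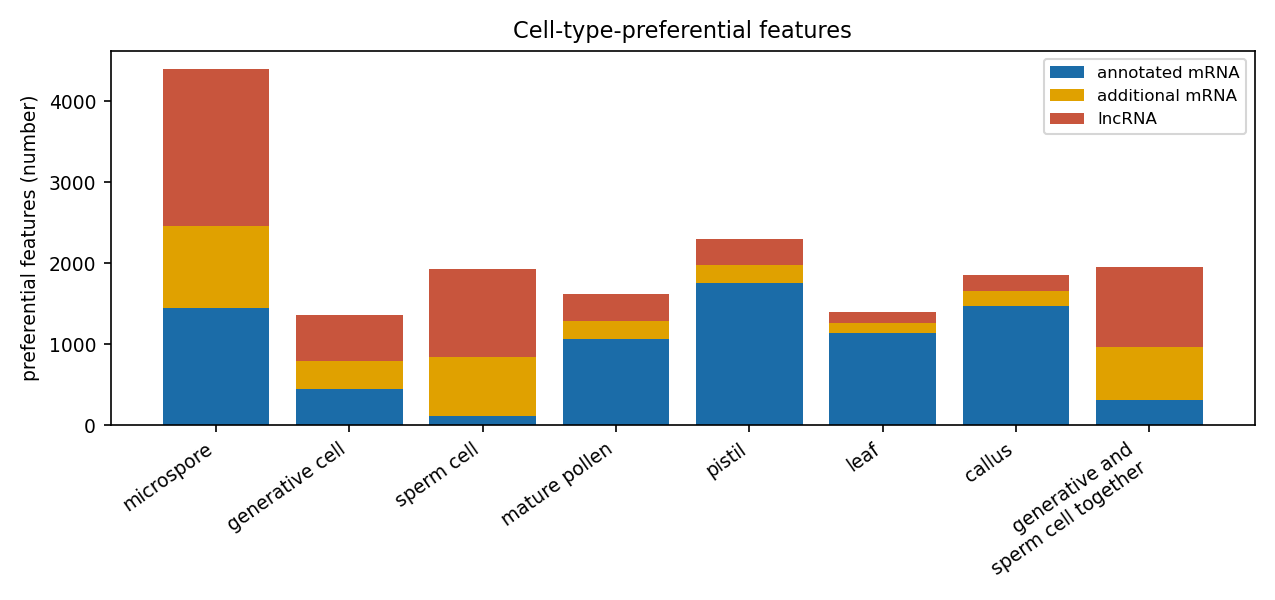
Number of features above all other cell types, divided into annotated mRNAs, additional mRNAs and lncRNAs; the last bar holds features above the other 5 cell types in both generative and sperm cells. Sperm cells have 119 annotated mRNAs and 1090 lncRNAs.

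lncRNAs were more restricted to single cell types than mRNAs as a whole, but hardly more than additional mRNAs. The tau index, which is 0 for even and 1 for single-group expression, had a median of 0.923 over 11015 lncRNAs and 0.708 over 27047 mRNAs, a difference of 0.215 (permutation p = 1e-05, the smallest that the permutations can give). Features are not independent replicates, so the permutation p-values here are likely too small. Matched on the highest group mean, 10043 lncRNAs and as many mRNAs had medians of 0.921 and 0.831, a difference of 0.0894 (permutation p = 1e-05). Among features with a group mean of 5 FPKM or more the matched difference was 0.214. There the unmatched medians were 0.870 for lncRNAs, 0.868 for additional mRNAs and 0.617 for annotated mRNAs. The mRNAs were of 2 kinds in this respect, with a median of 0.647 for the 20272 annotated and 0.909 for the 6775 additional mRNAs. lncRNAs were not tested against additional mRNAs alone. Both may be loci chosen from reads of these libraries, a candidate explanation taken up below. lncRNAs made up 34.25 ± 0.605% of the summed FPKM in generative cells, 34.8 ± 4.98% in sperm cells and 17.9 ± 0.681% in microspores, but 5.41 ± 2.95% in mature pollen and 5.32 ± 0.0717% in leaf (SD, n = 3). Pistil and callus lay between leaf and microspores, at 11.66 ± 0.0502% (n = 3) and 13.23 ± 0.34% (n = 2). Without the 10 most abundant features, an alternative chosen after seeing the data, the shares were 19.8% in generative cells, 21.8% in sperm cells and 15.7% in microspores. In the other groups they were 5.80% in mature pollen, 7.43% in leaf, 7.2% in pistil and 7.67% in callus.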

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

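The alternatives with callus 2 and 3 kept apart, scaling within groups, the gene-by-gene estimate for the planned array weights, the removal of features listed at 0, the removal of the 10 most abundant features and the class sets were chosen after seeing the data. The count of features called stayed within 1.5 times its reported value in every comparison and alternative except these: with a pseudocount of 0.1, sperm against generative cells gave 12573 and generative cells against mature pollen 18508; with quantile normalization, mature pollen against microspores gave 12521; with no fold threshold, sperm against generative cells gave 11441. The cause was not tested, apart from the last, where dropping the fold threshold adds features by construction. Similar totals did not mean the same features. Of the 20279 calls for generative cells against microspores, 13054 were also called under quantile normalization and 13276 under upper-quartile scaling. For mature pollen against microspores these were 9663 and 11666 of 20254, and for sperm cells against sporophytic tissue 14479 and 14844 of 20809. The other 2 comparisons kept 6138 and 6653 of 6993, and 10056 and 10350 of 11582. Leaving out 1 replicate gave 20132 to 20253 calls for generative cells against microspores, 6713 to 7470 for sperm against generative cells, 20084 to 20389 for mature pollen against microspores, 11445 to 11636 for generative cells against mature pollen and 20694 to 20879 for sperm cells against sporophytic tissue. Without sperm cell replicate 2 the split between sperm and generative cells was 3697 higher and 3161 lower. A fit of the compared groups alone gave 4826 calls for this comparison instead of 6993, a loss that lies inside the bound of 1.5 times.

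The replicate numbers did not pair the samples: in no comparison did all same-numbered pairs have deviations correlated above 0.1, and samples did not all correlate best with their own number. With the replicate block, the counts of calls were 20283, 7012, 20253, 11584 and 20807 in the order above. Count-based tests with their size factors were planned as alternatives and not run, since the files hold no counts.

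For preferential features, a log2 fold change of 2 or more left 1700 for microspores, 268 for generative cells, 678 for sperm cells, 1014 for mature pollen, 849 for pistil, 564 for leaf, 885 for callus and 878 for the germ cell pair, fewer by construction. A pseudocount of 0.1 gave 3283 for the pair. Quantile normalization gave 2665 for microspores, 2589 for mature pollen, 1137 for pistil and 3426 for the pair, for which the cause was not tested.

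Expressed mRNAs depended on the minimum by construction. At 0.1 FPKM there were 30293.0 in microspores, 20573.3 in generative cells, 15454.0 in sperm cells, 12169.0 in mature pollen and 25735.0 in callus. At 5 FPKM there were 9424.0, 4074.3, 3548.0, 2966.0 and 11057.0 in the same groups and 8216.3 in leaf. Expressed lncRNAs numbered 18846.3 in microspores, 11569.3 in generative cells, 7433.7 in sperm cells, 3424.7 in mature pollen, 13862.3 in pistil, 7081.3 in leaf and 11076.5 in callus at 0.1 FPKM, and 1139.7, 840.7, 1136.3, 255.7, 583.3, 351.3 and 559.0 at 5 FPKM. At 5 FPKM the sperm cell libraries ranged from 820 to 1588 lncRNAs and overlapped those of generative cells, 822 to 867, and of microspores, 1034 to 1257, so fewer lncRNAs in sperm cells than in microspores were not seen at that minimum. At 0.1 FPKM the callus samples had 15482 lncRNAs (library 1, with its low values) and 6671 (libraries 2 and 3), the latter below the leaf mean. At 0.1 FPKM sperm and generative cells did not overlap, with 13089 to 17747 against 20276 to 20981 mRNAs and 5757 to 8962 against 11491 to 11698 lncRNAs. At 5 FPKM pistil had 12216.3 mRNAs and callus more than microspores. Values near 0.1 FPKM rest on few fragments. With a pseudocount of 0.1, the mean correlation between replicates was 0.9801 in generative cells, 0.991 in pistil and 0.9837 in leaf.

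Among 64 named features and comparisons, 1079 of 1093 alternatives kept direction and call and 14 lost the call, none with a change of direction. The tau of lncRNAs stayed above that of mRNAs as a whole in every alternative run, with differences from 0.2153 to 0.2759. After matching, the differences ran from 0.0908 to 0.2142, the latter with a group mean of 5 FPKM or more. Of the class sets, those that passed with the preset correlation did not pass with an estimated correlation. Under quantile normalization 3 sets changed direction in mature pollen against microspores without passing: annotated mRNAs (adjusted p = 0.334), additional mRNAs with short frames (adjusted p = 0.234) and intergenic lncRNAs (adjusted p = 0.262); the cause was not tested.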

Other observations

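The tests of lncRNAs against additional mRNAs, of genomic DNA, of depth, of both explanations for the zeros and of other splits of the libraries were chosen or stated only after the result was seen.

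Some of the most abundant features were short lncRNAs of 1 exon. SlHei12G31376700.01 (chromosome 12, 2119041 to 2119345, plus strand, 305 nt) averaged 28217 FPKM in generative cells, 28548 FPKM in sperm cells and 187 FPKM in mature pollen. It was abundant in the other groups too, at 9759 FPKM in microspores, 7254 in callus, 5814 in pistil and 1256 in leaf. A feature matching the petunia defensin DEF_PETIN, a small cysteine-rich antimicrobial peptide, averaged 1399 ± 192 FPKM in pistil (SD, n = 3) and 0.74 ± 0.33 FPKM in microspores, and was listed at 0 in every library of generative cells, sperm cells, mature pollen and callus.

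Additional mRNAs and lncRNAs were called higher in sperm cells than in sporophytic tissue more often than annotated mRNAs (3486 of 13001 against 1577 of 19848). As pooled classes, lncRNAs and additional mRNAs did so alike (Fisher's exact odds ratio 1.001, 0.924 to 1.08). Inside the classes the shares differed. They were 29.8% for intergenic lncRNAs and 7.95% for lncRNAs overlapping a gene model on the same strand. For additional mRNAs they were 34.6% with short and 20.4% with partial frames. Whether additional mRNAs code for protein was not tested, so the pooled ratio does not decide on the non-coding nature of lncRNAs as a cause. A lower level is argued against, since the odds ratio after matching on the highest group mean was 9.361 (8.40 to 10.5). A candidate explanation is that these loci were chosen from reads of these libraries: features whose only evidence tags carry the label test_wlq were called higher in 34.42% of 8957 cases, against 6.51% of 2258 features without that tag (odds ratio 7.536, 6.34 to 9.02). Features without the tag were called higher no more often than annotated mRNAs, at 7.95% (odds ratio 0.807, 0.673 to 0.962). The excess over annotated mRNAs was thus seen only with the tag. That the tag marks assemblies of the study's own reads is inferred from its name and is not documented in the files. The tag may also mark loci truly limited to germ cells, and a biological difference between the cell types stays open and untested.

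Callus library 1 carried low values at features under 0.02 FPKM in callus 2 and 3 (median 0.0726 FPKM over 4995 features of at least 700 nt). Deeper sequencing is argued against, as its estimated fragments were 0.94 times the mean of the others. Genomic DNA reads may contribute, since the median FPKM was nearly flat over feature length (ratio 1.203 of features over 2500 nt to those of 700 to 1200 nt, 1.06 to 1.27). Transcription particular to that culture stays open, with an index of dispersion of 3.506 (2.91 to 4.47) whose interval includes the bound of 3 set for it. The index was 1.743 without the highest 5% of features and 2.697 from the median, and it was 1005 in microspore library 1.

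In 10 features a library was listed at 0 beside at least 100 FPKM in another library of its group, 8 of them in mature pollen, 1 in pistil and 1 in callus. Counting chance alone is an unlikely source of these zeros, since a median of 194300 fragments per kb would be expected in the library at 0. Choosing features at 100 FPKM nearly ensures such a value, so this was not a separate test. Failed estimates at very abundant loci are a candidate explanation, as the highest values had a median percentile of 95.99 among features reaching 100 FPKM in their group, with the callus feature SlHei10G28891600.01 apart at 13.29. No biological explanation was tested.

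In the comparisons of 3 libraries against 3, only 10 splits exist, too few for a share under 0.05. The real split of generative cells against microspores gave 20279 calls and the highest other 1, that of sperm against generative cells 6993 and 7, that of mature pollen against microspores 20254 and 0, and that of generative cells against mature pollen 11582 and 0. For sperm cells against sporophytic tissue, 1 of 100 splits drawn, the real one, gave as many as 20809 calls, and the highest other gave 12293, which points to a structure of the samples. For preferential features 1 of 100 drawn groupings, the real one, gave as many as 14863, with 1483 as the highest other. That share speaks only against group labels without meaning. The drawn groupings mix libraries of unlike tissues, so the real one was nearly bound to give the most calls. No conclusion on chance in single calls is drawn from it.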
